A study of Mus musculus with 2 samples.

How the data were processed

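PolyA RNA sequencing of mouse liver was analysed in 2 libraries, 1 per group, taken from FVB/N mice after hydrodynamic injection of c-Myc. The labels give the groups by treatment, which was either none or TSA. RNA was extracted with the mirVana kit and sequenced by a service company, per the labels' protocols. Trimmomatic, HISAT2, Bowtie2 and DESeq are named in the submitters' processing notes, with no roles or versions. The genome build, annotation, counting tool and strand setting are not given in the sources used here.

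The deposited counts are whole numbers of reads per gene symbol, unscaled, for 21878 symbols in each library, per the file headers and values. The deposited FPKM values are those counts divided by gene model length and by the total of the same library. Dividing out the counts gave a gene model length that was whole and equal in both libraries, within 0.1 base, for all 14271 genes with counts in both. No row lacked a gene name, no symbol was repeated and no mitochondrially encoded symbol was listed, so the share of mitochondrial reads could not be computed. Of the symbols 20654 matched the gene names of GENCODE M21, and a few list members were matched through older symbols. Because the authors' build is not given, no coordinates are printed.

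Total counts were 17281523 (untreated) and 17088227 (TSA). Library sizes were scaled by TMM in edgeR 4.0.16 under R 4.3.3, with factors of 1.34 for the untreated and 0.744 for the TSA library. TMM assumes that most genes do not differ, and DESeq2 1.42.0 size factors, upper quartiles and total counts were run as alternatives. Relative to total counts TMM moved every log2 ratio by 0.85. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

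No test across conditions is possible with 1 library per group, and no p-value is given. A gene was tested if it had at least 20 counts summed over both libraries, which left 13027 genes. The ratio is TSA over untreated, and a ratio under 1 is given as its inverse, as a fold lower. The 95% interval of each ratio is the exact conditional binomial interval (Clopper-Pearson). It covers counting error only, since reads without molecular identifiers are not independent molecules and the variation between animals is not measured. A gene is called higher or lower at a ratio of at least 2 in that direction with an interval that excludes 1. A count of 0 was set to a floor of 3 counts (0.129 CPM in the untreated and 0.236 CPM in the TSA library after scaling). The ratio then depends on that floor, and its 95% interval can start at a smaller difference.

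Before the data were examined, 47 gene lists were fixed from textbook knowledge of liver biology, of which 45 had at least 3 members tested. The mitochondrially encoded list had no listed member and the Y-linked list no member with enough counts. A list is described by its median log2 ratio relative to the median of all genes. The percentile of that median comes from 10000 random lists of the same size matched on mean expression in 20 bins. A list stands above or below random lists when its median lies outside their central 95%. By this rule 24 lists stood above and 6 below. For lists fixed in advance and named without a percentile in the text, the percentile was 0 or at least 99.93. Lists share members, and genes are not replicates.

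The genes named were fixed by rule before the data were examined. They are *Myc*, *Adh4* and the Akt genes; the 12 highest and 12 lowest ratios among called genes with at least 100 counts in the higher library, leaving out predicted models, pseudogenes and unnamed loci; in each list, among members with at least 50 summed counts, the 2 with most counts and the 2 with the largest difference; and the 10 genes of highest CPM in each library. Exceptions are named where they occur, and some genes that the rule selects are not reported here. Reads of close paralogs (the Mup, Cyp2c, Cyp3a, Cyp4a, Sult2a, Serpina, Saa, Orm and globin families) may be split between copies, and overlapping or antisense genes may share reads.

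The calling was tested on simulated data for TSA against untreated. Counts were drawn for 13040 genes with known changes and no variation between animals. Of 99 genes changed 3-fold 95 were called in the right direction, as were all 97 changed 8-fold, and 31 of 12844 unchanged genes were called. The intervals held the simulated ratio for 95.6% of genes. Few genes were changed, as many up as down, so the assumption of TMM held in the simulation. It therefore does not test the calls where much of the transcriptome differs and the calls depend on scaling. Alternatives were other scalings, the deposited FPKM with 0.1 added, other count minimums, a prior count of 2, thresholds of 1.5-fold and 4-fold, an interval bound of at least 2-fold, random lists without matching, and the untreated library thinned to the TSA total. After the data were seen, a correction for gene model length and 7 further gene lists were added.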

Results

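Messenger RNA from the liver of FVB/N mice was profiled by polyA RNA sequencing after c-Myc had been delivered by hydrodynamic injection, a rapid tail vein injection that brings DNA into hepatocytes. Each group was represented by 1 library, 1 liver sample without treatment (untreated) and 1 with TSA. The labels give the tissue as liver and do not state whether a sample was whole liver, tumour or a mix, nor whether it came from a single animal or a pool. Ratios of hepatocyte, fetal and proliferation genes therefore hold any difference in tissue makeup between the samples. The untreated library held 17281523 counts over 15292 detected genes and the TSA library 17088227 counts over 14958 detected genes. With 1 library per group the differences have no replicate check, and the 95% intervals given in parentheses cover counting error only. A gene is called higher or lower in the TSA library by size alone, at a ratio of at least 2 with an interval that excludes 1. The submitters' title ties TSA to slower liver tumour development driven by c-Myc and to phosphorylated AKT and ADH4. Transcript counts measure neither tumour burden nor AKT phosphorylation.

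The libraries differed over much of the transcriptome. Of 13027 genes tested, 3382 were higher and 3573 were lower in the TSA library, and 6072 were neither. Among the gene lists fixed in advance, female-biased, drug metabolism and central vein genes had the highest medians, and cell division, DNA replication and MYC target genes the lowest. *Alb*, the serum albumin gene, took 8.35% of counts with TSA and 0.264% without it. *Afp*, the alpha-fetoprotein gene, was 413-fold (347 to 497) lower with TSA. Differences of at least 10-fold were found in 1017 genes higher and 716 genes lower, and of at least 100-fold in 253 higher and 74 lower. The balance of higher and lower calls depended on scaling. With TMM, which assumes that most genes do not differ, 26.0% of the genes tested were higher and 27.4% lower, so 48.6% of the called genes were higher. With total counts 2084 were higher and 6339 lower, so 24.7% of the called genes were higher. The median log2 ratio of all genes was -0.11 with TMM and -0.96 with total counts, so list medians below are given relative to the TMM median of all genes.

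Mouse *Myc*, the gene that codes for c-Myc, had 55 counts (1.33 FPKM) in the untreated library and 763 counts (18.6 FPKM) in the TSA library. It was 25.3-fold (19.2 to 33.9) higher with TSA, and 14-fold higher with total counts. Both libraries are labelled as injected, the sources used here do not say from which species the injected sequence came, and the count at the mouse gene therefore does not check either label. MYC target genes, many of them of the nucleolus and ribosome assembly, were lower as a group: 30 of 32 were lower, none was higher, and their median log2 ratio was -2.35. Among them *Ncl*, for nucleolin, was 8.66-fold (8.34 to 8.98) lower, *Npm1*, for nucleophosmin, 11.9-fold (11.3 to 12.5) lower, and *Hspd1*, a mitochondrial chaperone gene, 2.6-fold (2.54 to 2.65) lower. The remaining 2 members, named after their values were seen, were *Hspe1* at 1.72-fold and *Tfrc* at 1.95-fold below the untreated level. The MYC network list holds *Myc* itself, its relatives and genes of factors that pair or compete within this network. Of its 11 genes 4, *Myc* among them, were higher and 2 lower with TMM, against 3 and 5 with total counts. *Max*, for the partner of MYC, was 2.4-fold (2.15 to 2.69) lower and *Mlxipl*, for the glucose-responsive factor ChREBP, 4.18-fold (4.0 to 4.36) higher. The median of the network list, 0.93, lay within the range of random lists (percentile 93.17).

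Genes of cell division were lower without exception among the 25 tested, with a list median of -5.92. *Top2a*, for the topoisomerase that untangles replicated DNA, was 99.2-fold (76.5 to 131) lower with TSA, *Ccnb1*, for cyclin B1, 137-fold (81.3 to 250.0) lower, and the proliferation marker *Mki67* 47.6-fold (39.3 to 58.1) lower. The smallest difference in this list was 9.9-fold and the largest 137-fold. Of 25 DNA replication genes 24 were lower, with a median of -3.21. *Mcm6*, for a subunit of the replicative helicase, was 25.1-fold (21.3 to 29.7) lower and *Rrm2*, for a subunit of the enzyme that makes deoxyribonucleotides, 26.1-fold (21.3 to 32.3) lower. *Tk1*, named after the values were seen because it was the sole member not called, was 1.33-fold (1.21 to 1.46) below the untreated level. Both list medians lay below every matched random list.

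*Adh4*, for the class II alcohol dehydrogenase that the series title names, had 43 counts (1.90 FPKM) without treatment and 1974 counts (88 FPKM) with TSA. It was 83.8-fold (62 to 116) higher, and 46.4-fold higher with total counts. It moved with its family: 15 of 18 alcohol, aldehyde and retinol dehydrogenase genes were higher with TMM and 12 with total counts, and the median log2 ratio was 3.68. *Adh1*, for the main liver alcohol dehydrogenase, was 159-fold (145 to 176) higher, *Aldh2*, for the mitochondrial enzyme that clears acetaldehyde, 12.7-fold (12.3 to 13) higher, and the retinol dehydrogenase genes *Rdh7* and *Rdh16* 251-fold (211 to 300.1) and 349-fold (183 to 764) higher. *Aldh1b1* was the sole member lower, by 3.42-fold (3.29 to 3.55), and *Aldh5a1* and *Aldh9a1* were neither; these 3 are named after their values were seen. Many other genes of mature hepatocytes were higher in the same library, and 253 genes were higher by at least 100-fold.

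*Akt1* and *Akt2* differed little beside these. *Akt1* was at 1.07-fold (1.01 to 1.14) of the untreated level with TMM, *Akt2* at 1.36-fold (1.29 to 1.45), and neither was called; with total counts both ratios lay under 1, at 0.593-fold and 0.756-fold. Of 24 genes of the PI3K, AKT and mTOR pathway 7 were higher and 1 was lower with TMM, and 1 higher and 7 lower with total counts. Its median relative to all genes, which a common scaling factor does not move, was 0.42 and lay within the random range (percentile 88.2). The examples were *Irs1*, for an insulin receptor substrate, at 6.68-fold (5.67 to 7.9) higher, and *Pik3r1*, for the regulatory subunit p85, at 2.67-fold (2.48 to 2.88) higher, or 1.48-fold with total counts. *Inpp4b* was the lower member, named after its value was seen. Genes that FOXO factors switch on when AKT is inactive were mostly higher, 10 of 15 with TMM, with a median of 2.97, and 8 higher and 3 lower with total counts. *Pck1*, for the gate enzyme of gluconeogenesis, was 579-fold (509 to 662) higher, *Igfbp1* 21.5-fold (20.6 to 22.4) higher and *Pdk4*, for a kinase that turns off pyruvate oxidation, 1307-fold (816 to 2244) higher. With TMM *Cited2* alone was lower. *Cdkn1b* and *Sesn1*, at 1.63-fold and 1.28-fold below the untreated level, and *Sesn3* and *Insr*, at 1.39-fold and 1.79-fold of it, were not called. *Cited2*, *Cdkn1b*, *Sesn1* and *Sesn3* are named after their values were seen. Of the 15 FOXO targets 5 also stand in other lists used here. Their median was near those of the hepatocyte secreted protein and transcription factor list (2.90) and the gluconeogenesis and glycogen list (3.08). The list therefore gives no measure of AKT activity apart from hepatocyte content.

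Hepatocyte function genes were higher with few exceptions, in the library in which endothelial and erythroid markers were also higher. All 26 genes of cytochrome P450 and drug metabolism were higher, with a median of 8.21, and they ranged from 4.89-fold to 2227-fold. *Cyp2e1*, for the ethanol-oxidising P450, was 437-fold (403 to 475) higher, *Cyp3a11* 128-fold (119 to 139) higher and *Cyp2c54* 690.2-fold (477 to 1039) higher. Of 25 genes of secreted proteins and hepatocyte transcription factors 22 were higher and none lower with TMM (median 2.90), and 18 higher and 2 lower with total counts. *Alb* was 57.1-fold (56.6 to 57.6) higher, *Trf*, for transferrin, 6.53-fold (6.48 to 6.57) higher and *Tat*, for tyrosine aminotransferase, 1129-fold (928 to 1387) higher. The transcription factor genes *Foxa2* and *Foxa3*, named after their values were seen, were neither with TMM. All 19 genes of bile acid synthesis and transport were higher (median 6.62), with *Slc27a5*, for the bile acid CoA ligase, at 252-fold and the organic anion transporter genes *Slco1a1* and *Slco1b2* at 306-fold and 293-fold. All 26 acute phase genes were higher with TMM and 24 with total counts (median 5.0), including *C3*, for complement component 3, at 12.1-fold (11.9 to 12.2) and *Fga*, for a fibrinogen chain, at 3.86-fold (3.81 to 3.91). Glutathione transferases and NRF2 targets were higher in 12 of 17 cases (median 3.02), with *Gsta3* 45.8-fold (43.2 to 48.6) and *Gstm1* 14.9-fold (14.3 to 15.6) higher. The 2 lower members were *G6pdx* and *Gstp1*, named after their values were seen.

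Genes of both ends of the liver lobule were higher. Near the portal vein 16 of 17 marker genes were higher (median 4.08), with *Cps1*, for the first enzyme of the urea cycle, at 21.1-fold (20.6 to 21.6) and *Etnppl* at 314-fold (144 to 858). Near the central vein all 18 were higher (median 7.20), with *Glul*, for glutamine synthetase, at 6.89-fold (6.67 to 7.13), *Cyp2c29* at 581-fold (471 to 727) and *Cyp2c50* at 566-fold (423 to 776). Targets of WNT and beta-catenin in the liver were higher in 13 of 15 cases (median 5.79), with *Cyp1a2* at 408-fold (324 to 521). Liver genes with a sex bias were higher in both directions of that bias. Male-biased genes were higher in 16 of 19 cases (median 5.70), with *Mup7* at 898-fold (473 to 1965), and the exceptions, named after their values were seen, were *Cyp4a12a* at 7.76-fold (5.36 to 11.6) lower, *Gstp1* at 2.08-fold (1.96 to 2.22) lower and *Cyp4a12b*, with 408 counts without treatment and 2 with TSA, a ratio of 112-fold (30.7 to 926). All 18 female-biased genes were higher (median 8.25), with *Sult3a1* at 803-fold (591 to 1119). The Y-linked genes *Ddx3y*, *Eif2s3y*, *Uty* and *Kdm5d* had 0 counts in either library, which allows up to 3 counts each, and *Xist* was not among the listed symbols. The hepatocyte lists overlap: 15 of the 18 central vein genes, 11 of the 17 portal genes and 10 of the 26 drug metabolism genes also stand in another list. The same holds for 7 of the 15 WNT and beta-catenin targets, *Cyp1a2* among them, so these lists are not separate measurements.

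Genes of fuel metabolism split by pathway. Gluconeogenesis and glycogen genes were higher in all 14 cases (median 3.08), with *G6pc*, for the enzyme that releases glucose, at 99.1-fold (89.5 to 110.2) and *Fbp1* at 302-fold (246 to 374); with total counts 8 of them passed the size rule. Urea cycle and amino acid breakdown genes were higher in 23 of 25 cases with TMM (median 4.05; 20 higher and 2 lower with total counts), with *Tdo2*, for the tryptophan-degrading dioxygenase, at 436-fold (339 to 570.3), while *Gldc* was lower and *Sdsl* neither, both named after their values were seen. Fatty acid and triglyceride synthesis genes were higher in 18 of 21 cases with TMM (median 2.18; 13 higher and 0 lower with total counts): *Scd1*, for the stearoyl-CoA desaturase of adult liver, was 22.1-fold (21.5 to 22.8) higher and *Thrsp* 357-fold (296 to 434) higher, and *Fasn*, for fatty acid synthase, was 2.21-fold (2.17 to 2.25) higher with TMM but 1.22-fold with total counts. Fatty acid oxidation genes were higher in 17 of 23 cases with TMM (median 2.51; 15 higher and 1 lower with total counts). *Cyp4a31* had 0 counts without treatment and 150 with TSA, 91.3-fold higher against a floor of 3 counts, with an interval from 73.3-fold upward. Glycolysis genes were lower as a group, 11 of 20 lower and 5 higher with TMM (median -1.28, percentile 0.03), and 5 higher and 15 lower with total counts. *Ldha*, for lactate dehydrogenase A, was 3.02-fold (2.94 to 3.11) lower and the lactate exporter gene *Slc16a3* 44.6-fold (25.4 to 86.5) lower. Cholesterol synthesis genes were higher in 10 of 24 cases and lower in 1 with TMM, against 5 and 3 with total counts, and their median of 0.87 lay within the random range (percentile 96.59). *Tm7sf2* was 10.3-fold (9.31 to 11.5) higher and *Insig1*, for a sterol sensor partner, 7.81-fold (7.38 to 8.27) higher.

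Fetal liver and liver cancer markers were split, 12 of 23 lower and 8 higher, with a median of -1.07 (percentile 0.5), and 5 higher and 13 lower with total counts. Among the higher members, named after their values were seen, were *Prom1* at 58.4-fold (27.9 to 147), *Lcn2* at 18.4-fold (14.5 to 23.6), *Spp1* at 13.1-fold (10.3 to 16.9) and *Cd24a* at 8.98-fold (4.9 to 17.8). Without treatment they were scarce, at 0.302, 3.27, 3.27 and 0.56 CPM. *Prom1*, *Lcn2* and *Spp1* also stand in the female-biased, acute phase and cholangiocyte lists, in that order. *Afp* had 94320 counts in the untreated library and 125 in the other. The fetal growth factor gene *Igf2* was 41.5-fold (39.2 to 44.1) lower and *Scd2*, for a desaturase of the developing liver, 81-fold (72.9 to 90.2) lower. *H19* was not among the listed symbols. *Lrp2*, for the endocytic receptor megalin, had 1581 counts without treatment and 1 with TSA, a ratio of 866-fold (155 to 34238). The other genes with the smallest ratios, by the rule fixed in advance, were *Fam169a*, *Fabp3*, *Peg10*, *Rcor2*, *Dnajc6*, *Depdc1b*, *Rpp25*, *Dusp9*, *Car12* and *Aqp3*. *Peg10*, an imprinted gene derived from a retrotransposon, was 545-fold (212 to 1999) lower, and *Dusp9*, for a MAP kinase phosphatase, 275-fold (164 to 504) lower. Among those at the other end were *Mup13*, *Cyp4a32*, *Cyp2b10*, *Sult2a5*, *Pdk4*, *Ces3b*, *Mup18*, *Tat*, *Mup12*, *Slc22a26* and *Mup9*. *Mup13*, of the major urinary protein family, had 1 count without treatment and 3362 with TSA, a ratio of 6136-fold (1100.5 to 242421), and *Cyp2b10*, for a drug-inducible P450, had 1 and 1220, a ratio of 2227-fold (399 to 88015). *Mup9* rested on more counts, 169 and 83543, and was 902-fold (776 to 1055) higher. Genes of the Mup, Cyp2c, Cyp3a, Cyp4a and Sult2a families share reads with close copies, and the way shared reads were counted is not given in the sources used here, so ratios of single members are uncertain.

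The most abundant transcripts differed as well. In the untreated library the highest CPM belonged to *Eef1a1*, *Afp*, *Trf*, *Igf2*, *Hsp90ab1*, *Eef2*, *Scd2*, *Hspa8*, *Ncl* and *Rpl4*, most of them genes of translation, protein folding and the fetal liver. In the TSA library it belonged to *Alb*, *Trf*, *C3*, *Ahsg*, *Apoe*, *Cyp2e1*, *Apob*, *Pzp*, *Serpina3k* and *Gc*, of which all but the P450 gene code for secreted plasma proteins. *Trf* stood in both sets. The 20 most abundant genes took 7.23% of counts without treatment and 22.7% with TSA. *Rpl4*, for a ribosomal protein, was 3.26-fold (3.18 to 3.33) lower with TSA, and *Eef1a1*, for the elongation factor, was 1.53-fold (1.52 to 1.54) below the untreated level, which does not pass the rule with TMM but does with total counts at 2.76-fold. *Serpina3k* was 643-fold (579.7 to 716) higher and *Pzp* 106-fold (102 to 111) higher.

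**Figure D1:**
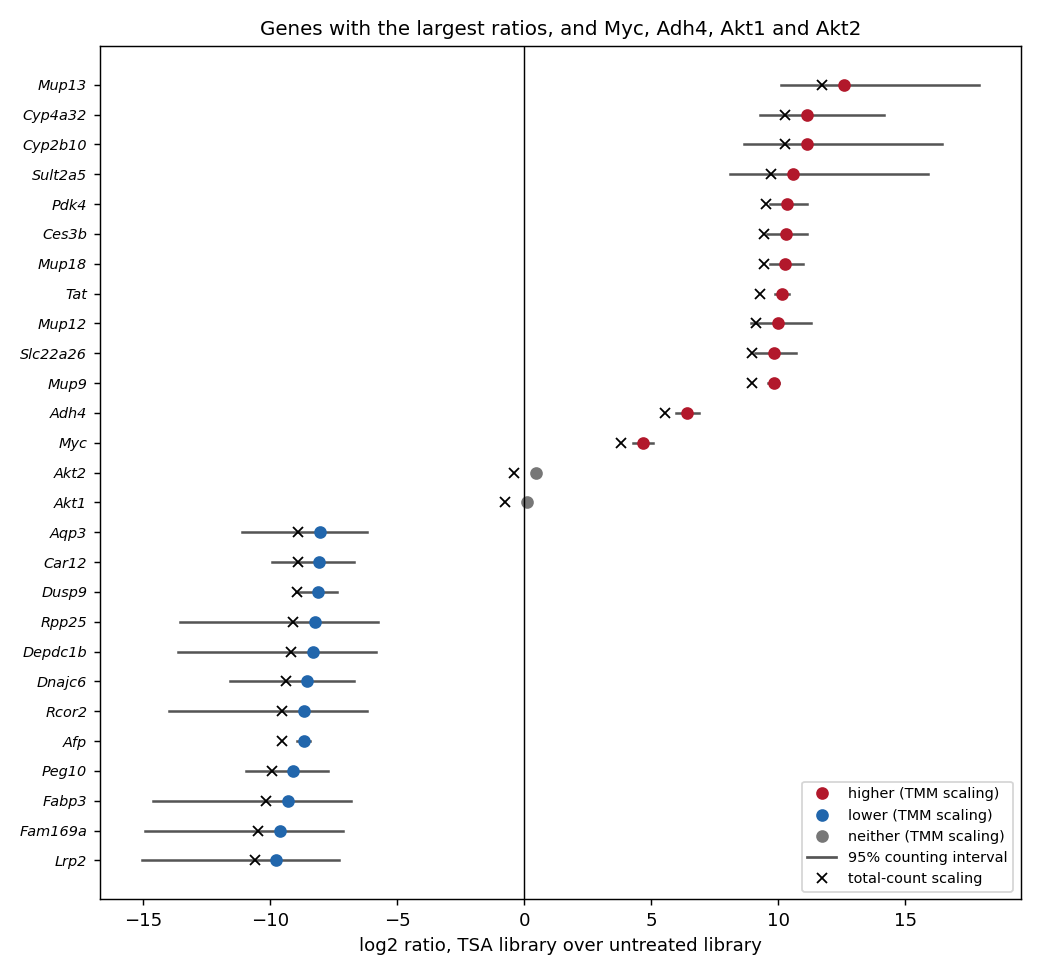
Log2 ratios of the TSA library over the untreated library for Myc, Adh4, Akt1, Akt2, the 12 lowest genes and most of the 12 highest genes chosen by the rule fixed in advance. Points are TMM-scaled ratios with 95% counting intervals and crosses are ratios scaled by total counts, which lie 0.85 lower for each gene; Akt1 and Akt2 change sign between the scalings, and Adh4 and Myc stay above 0 under both.

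Lists of stress and cell fate genes gave mixed results. Targets of p53 were lower as a group, 10 of 17 lower and 3 higher (median -1.25, percentile 0.36): *Bax*, for a pro-apoptotic pore protein, was 4.51-fold (3.93 to 5.21) lower, and *Btg2*, an antiproliferative gene, 17.6-fold (16 to 19.3) higher. Apoptosis regulators had a median of 0.28 and endoplasmic reticulum stress genes of 0.97, both within the random range (percentiles 85.8 and 95.86). In the stress list 9 of 20 genes were higher with TMM and 5 with total counts, among them *Herpud1* at 14.3-fold (13.6 to 15.1), and *Asns*, for asparagine synthetase, was lower by 116-fold (79.2 to 178). Among apoptosis genes 4 were higher and 5 lower of 20 with TMM, and 2 and 8 with total counts, with *Xiap*, for a caspase inhibitor, at 3.06-fold (2.85 to 3.28) higher, or 1.69-fold with total counts. Heat shock genes were also within the random range (median -0.23, percentile 21.77), with 3 higher and 4 lower of 14 with TMM and 2 and 8 with total counts; *Hspa1b*, for an inducible chaperone that shares most of its sequence with *Hspa1a*, was 11-fold (7.31 to 17) higher and *Hsp90ab1* 2.17-fold (2.14 to 2.2) lower.

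Histone deacetylase genes showed no common direction. Of 17 tested 6 were higher and 5 lower with TMM, and 1 and 8 with total counts (median 0.05, percentile 61.87). *Hdac1* was 3.69-fold (3.27 to 4.18) lower and the mitochondrial deacylase gene *Sirt3* 3.67-fold (3.32 to 4.06) higher. A list of genes that deacetylase inhibitors often raise had 8 members higher and 4 lower of 18 with TMM, and 4 and 6 with total counts. Its median was 0.51, within the random range (percentile 80.82). *Clu*, for clusterin, was 31.2-fold (29.4 to 33.1) higher, *Txnip*, for a glucose-responsive regulator of thioredoxin, 3.15-fold (3.06 to 3.24) higher and 1.75-fold with total counts, and *Cpt1c* 22.4-fold (12.7 to 43.6) lower. The labels abbreviate the treatment as TSA and do not spell the name out.

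Immune signalling, clock and immediate early genes stood above random lists. Interferon response genes were higher in 18 of 24 cases with TMM and 11 with total counts (median 1.77), with *Igtp*, for a GTPase induced by interferon gamma, at 10.5-fold (9.22 to 12) and *Zbp1*, for a nucleic acid sensor, at 8.35-fold (5.9 to 12.1). MHC class I and antigen presentation genes were higher in 11 of 13 cases with TMM (median 3.0; 9 higher and 0 lower with total counts), with *H2-K1* at 12.9-fold (12.1 to 13.7) and *B2m*, for the shared light chain, at 9.27-fold (9.0 to 9.55). Clock genes were higher in 13 of 17 cases with TMM (median 1.66; 8 higher and 2 lower with total counts), with *Per3* at 10.9-fold (9.33 to 12.8) and *Tef* at 4.78-fold (4.46 to 5.13); the time of day of collection is not given in the sources used here. Immediate early genes, which respond within minutes to growth factors and handling, were higher in 14 of 18 cases with TMM (median 3.05; 11 higher and 0 lower with total counts), with *Egr1* at 44-fold (39.5 to 49.2) and *Dusp1* at 21.9-fold (19.1 to 25.2).

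Markers of other cell types differed between the libraries too. Endothelial markers were higher in 15 of 18 cases with TMM (median 2.79; 12 higher and 2 lower with total counts), with the sinusoidal gene *Clec4g* at 119-fold (76.8 to 196) and *Dnase1l3* at 40.5-fold (32.6 to 50.8). Erythroid genes were higher in 8 of 9 cases with TMM (median 2.48, percentile 99.7; 7 higher and 1 lower with total counts), with the globin gene *Hbb-bs* at 4.71-fold (4.33 to 5.14). B and plasma cell markers were higher in 6 of 8 cases with TMM (median 2.96, percentile 98.15; 5 higher and 2 lower with total counts), with *Jchain* at 2.37-fold (1.8 to 3.12), or 1.31-fold with total counts, while the plasma cell gene *Mzb1* was 3.08-fold (1.44 to 7.57) lower. The whole B and plasma cell list held 264 counts without treatment and 312 with TSA. *Jchain* had 97 and 126 of them and *Cd22* 99 and 39, so the median rests on members with few counts. *Cd22* was 1.39-fold (0.951 to 2.07) below the untreated level, not called. With the deposited FPKM the median of these markers lay inside the random range, at 2.11 (percentile 97.48). Kupffer cell and macrophage markers went both ways, 9 higher and 3 lower of 20 with TMM and 6 and 7 with total counts (median 0.48, percentile 84.84): the resident Kupffer cell gene *Clec4f* was 44.3-fold (36.3 to 54.5) higher and the general macrophage gene *Lyz2* 2.16-fold (2.05 to 2.28) lower. Stellate cell, fibroblast and matrix genes were split likewise, 10 higher and 7 lower of 24 with TMM and 8 and 11 with total counts (median 0.37, percentile 84.83), with the stellate genes *Reln* 26.8-fold (22.5 to 32) and *Lrat* 22.9-fold (16 to 33.7) higher and *Col4a1*, for a basement membrane collagen, 9.07-fold (8.46 to 9.72) lower. Cholangiocyte markers had 6 members higher and 5 lower of 15 with TMM, and 4 and 8 with total counts (median -0.08, percentile 42.53), with *Krt7* 31.6-fold (17.1 to 66.3) lower. Dendritic cell markers (median 1.73, percentile 96.09), T and NK cell markers (median 1.14, percentile 78.71), neutrophil markers (median 2.37, percentile 91.55) and adipocyte and muscle genes (median 1.30, percentile 75.6) lay within the random range, over 8, 8, 5 and 3 genes tested. Of the T and NK cell markers 3 were higher and none lower with TMM, and 1 was higher and 2 lower with total counts. Pancreatic acinar and gut genes were higher in 11 of 13 cases (median 4.64), with *Ctrb1*, for chymotrypsinogen, at 1 and 154 counts, a ratio of 281-fold (49.7 to 11172), and *Cela1*, for an elastase, at 50 and 505 counts.

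Several small counts above rest on genes outside the naming rule, which are named here after their values were seen. In glycolysis the higher genes included *Pfkm* 8.15-fold, *Pklr* 7.84-fold and *Slc2a2*, for the hepatocyte glucose transporter, 11.8-fold. In the MYC network list *Mycl* and *Mxd4* were 4.18-fold and 2.74-fold higher. Among p53 targets *Fas* was 4.21-fold higher, and among apoptosis genes *Bcl2l1* and *Casp8* were higher and *Bak1*, *Bid*, *Bmf* and *Apaf1* lower. The sole lower gene of the interferon response was *Cxcl10*, by 4.03-fold. The lower genes among those often raised by deacetylase inhibitors included *Cdkn1a*, for the cell cycle inhibitor p21, by 3.23-fold (2.8 to 3.75), *Tubb2b* and *Gsn*. The other lower deacetylase genes were *Hdac2*, *Hdac6*, *Sirt1* and *Sirt6*. Among macrophage markers *Cd68* and *Gpnmb* were lower, by 3.42-fold and 4.58-fold, and among cholangiocyte markers *Epcam*, *Cldn4* and *St14*. *Vil1*, a gut epithelium gene, was 26.5-fold (13.3 to 61.8) lower.

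**Figure D2:**
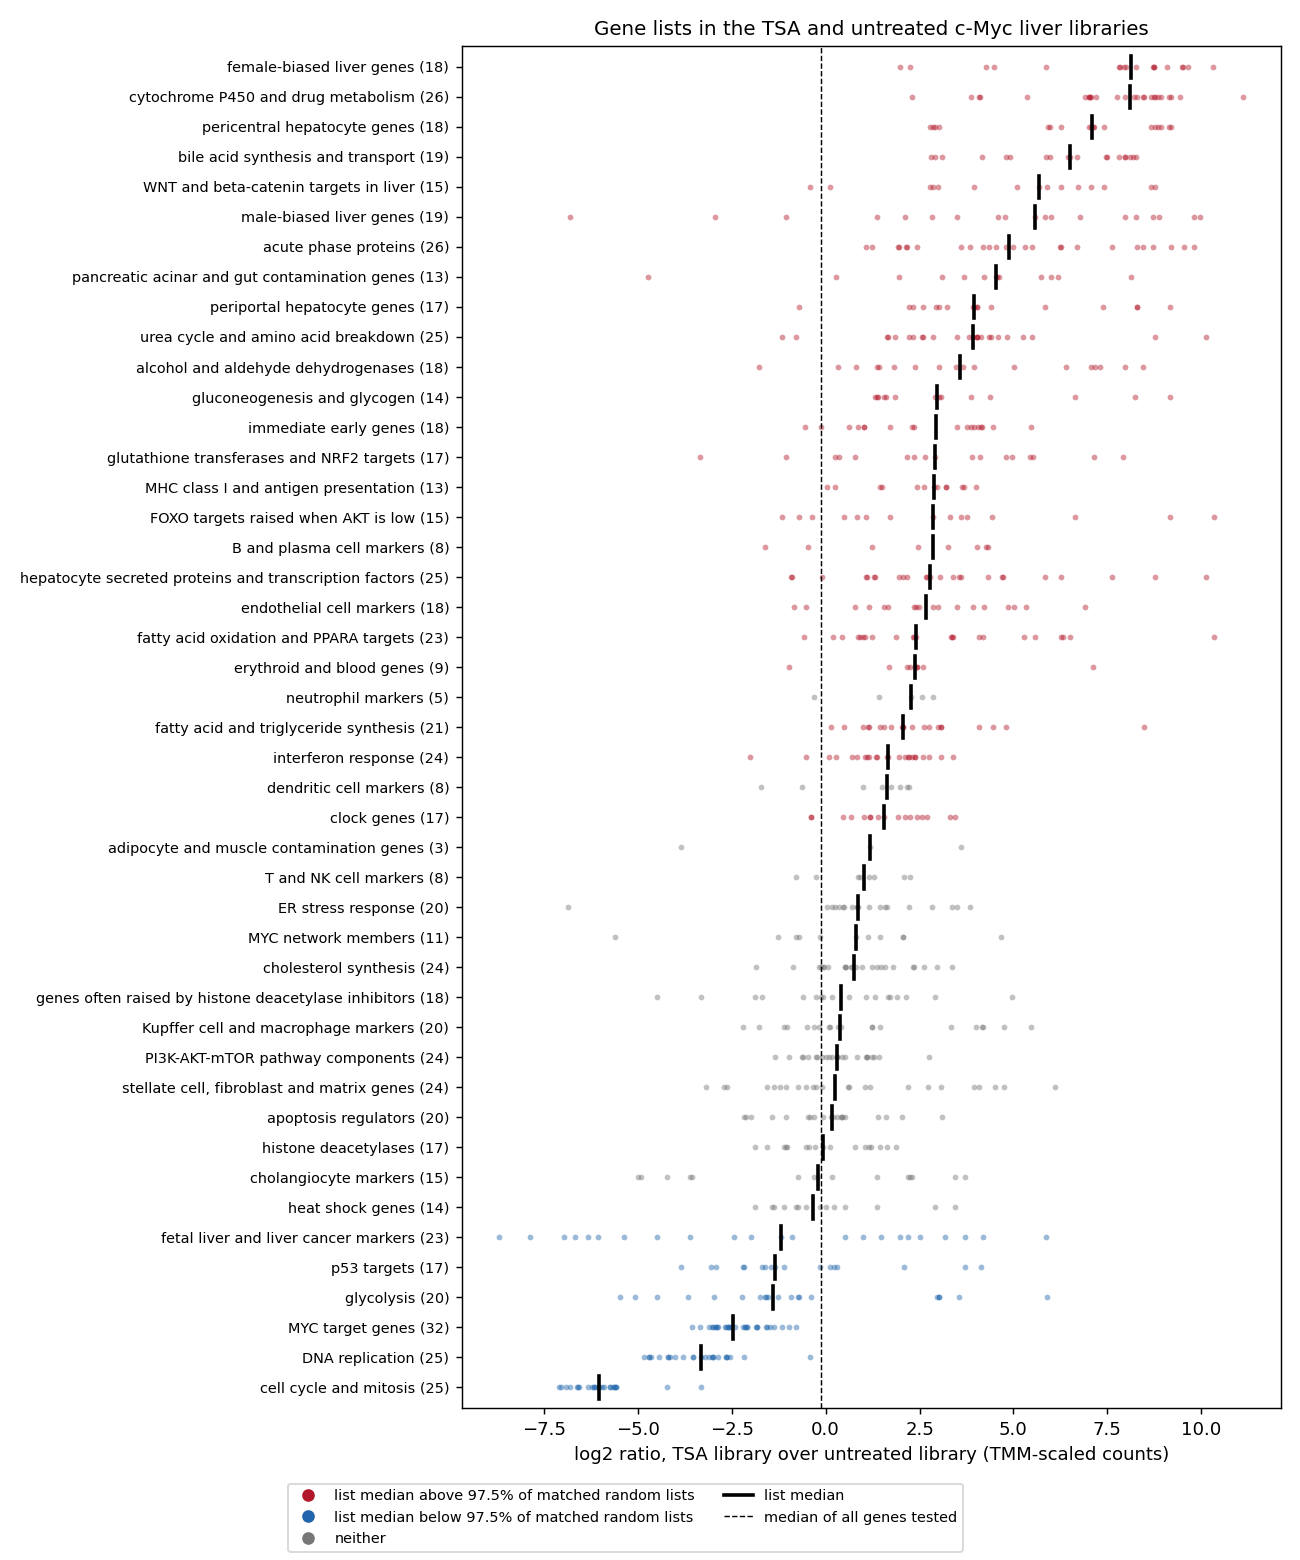
Log2 ratios of the TSA library over the untreated library (TMM-scaled) for the tested members of 45 gene lists fixed in advance, with the number tested after each name; each point is a gene, black bars are list medians and the dashed line is the median of all genes tested. Cell division, DNA replication and MYC target genes lie lowest, and female-biased, drug metabolism and central vein genes highest.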

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

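The correction for gene model length was chosen after the data were seen; the other alternatives were fixed before. Single genes were run under 9 alternatives, gene lists under 11 and counts of genes under 12. The scalings, the filters, the deposited FPKM and the prior count cannot turn the sign of a called gene by their construction, so they do not test it. Relative list medians can move with the FPKM, the filters, the prior count, thinning and the length correction, and under these no list median standing apart changed sign. With total counts 2084 genes were higher and 6339 lower, against 3382 and 3573 with TMM, so 24.7% and not 48.6% of called genes were higher; leaving out the 20 most abundant genes from the totals gave 5387 lower and a share of 30.8% higher. The deposited FPKM gave 1983 higher and 6186 lower. Both totals lower every log2 ratio by a constant. *Myc*, at 4.66 with TMM, stood at 3.81 with total counts, 4.09 without the 20 genes and 3.71 with FPKM, and *Adh4*, at 6.39, stood at 5.54, 5.81 and 5.46. A 4-fold threshold left 1951 higher and 1640 lower genes by its construction.

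Of 491 list medians recomputed, 484 kept their place inside or outside the random range; the filter at 100 counts left 4 of the 45 lists with too few members for a value. The 484 include the 45 values under each other scaling, which test nothing. They also include 45 values after thinning, which removed few counts from the untreated library. The deposited FPKM brought B and plasma cell markers inside it, at a relative median of 2.11. Outside it came neutrophil markers without a filter, at 1.82, and Kupffer cell and macrophage markers at 100 or more summed counts, at 0.98. Random lists not matched on expression put cholesterol synthesis (0.87), the ER stress response (0.97), neutrophil markers (2.37) and dendritic cell markers (1.73) outside the range. The cause was not tested for these. Of 2199 values of single genes, chosen by the rule or afterwards, 625 moved outside their counting interval. All moves came under other scalings or the deposited FPKM, which set a largely common shift against an interval that narrows with counts. Filters cannot move the ratio of a gene, so the number does not measure how robust the ratios are. A relative list median does not change with a common scaling factor, so other scalings test the counts of members and not the percentiles. No paired analysis was possible because each group has 1 library, and leaving out replicates was not run for the same reason. Depth limits genes with few counts: ratios that rest on 1 to 3 counts in the lower library have intervals that span more than 10-fold.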

Other observations

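The 7 gene lists, the genes of the first 2 paragraphs and the last, the correction for gene model length and the tests of explanations were chosen after the values were seen. The total-count scaling and the immediate early, fetal and Y-linked lists were fixed before. Genes that make serine, glycine and asparagine and import amino acids were lower with TSA, 9 of 12 with none higher (relative median -4.25). *Phgdh*, for the first enzyme of serine synthesis, was 182-fold (134 to 254) lower, *Psat1*, for the next, 119.6-fold (92.8 to 157) lower, and *Asns* 116-fold (79.2 to 178) lower. The machinery of translation was lower as well: 75 of 77 cytosolic ribosomal protein genes (relative median -1.49), 14 of 20 cytosolic aminoacyl-tRNA synthetase genes (relative median -1.30; *Aars* alone was higher, at 3.59-fold (3.42 to 3.77), and at 1.99-fold with total counts, not called) and 14 of 18 elongation and initiation factor genes (relative median -1.40). All 26 complement and coagulation genes were higher (relative median 3.71).

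Of 11 imprinted growth genes 8 were lower and 2 higher with TMM, *Plagl1* and *Ndn*, and 0 higher and 8 lower with total counts (relative median -1.87). *Dlk1* had 678 counts without treatment and 0 with TSA, 124-fold lower against a floor of 3 counts, with an interval from 100.4-fold upward. Of 7 genes of fetal RNA-binding proteins 6 were lower, including *Igf2bp3* at 102-fold (61.5 to 182), and *Igf2bp2* was higher at 7.67-fold (2.81 to 26). Some enzymes with a fetal or tumour form and an adult liver form were exchanged: *Pkm* was 33.6-fold (30.5 to 37.1) lower and *Pklr* 7.84-fold (7.32 to 8.4) higher. *Scd2* and *Scd1* were 81-fold (72.9 to 90.2) lower and 22.1-fold (21.5 to 22.8) higher. For *Mat2a* and *Mat1a* the adult gene was 32.8-fold (31.8 to 33.8) higher while *Mat2a* was 1.68-fold (1.59 to 1.78) below the untreated level with TMM, not called, and 3.03-fold lower with total counts.

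Cell division and MYC target genes were lower, and hepatocyte genes higher, in the same library. Gene model length is argued against, since all 30 lists that stood apart still did so after correction for it. A different share of tumour tissue in the samples stays open. Of 23 fetal liver and liver cancer markers 12 were lower and 8 higher with TSA. In the untreated library the higher members stood at 0.258 to 3.27 CPM and the lower ones at 4.82 to 4063 CPM. Of the 23 markers 5 also stand in other lists. The numbers of members on either side therefore decide nothing about that share. Markers of other cell types also bear on tissue makeup: endothelial markers were higher in 15 of 18 cases with TMM (relative median 2.79). Kupffer cell and macrophage markers and stellate cell, fibroblast and matrix genes lay within the random range. The endothelial markers go with a difference in makeup beyond an effect on tumour cells, but rest on 1 library per group. The pattern may come from less tumour in the TSA sample as well as from a treatment effect on tumour cells. With 1 library per group these cannot be told apart, and the treatment effect was not tested.

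*Myc* was higher with TSA while MYC target genes were lower. An immediate early response of the tissue at collection is a candidate explanation for the higher *Myc*. *Myc* belongs to the genes that respond early to stimuli, and the immediate early list had a relative median of 3.05. That list bears on *Myc* only and says nothing about the lower MYC target genes. Whether reads of the injected sequence were counted outside mouse *Myc* could not be decided: *Myc* in the untreated library was at 1.33 FPKM, but the injected sequence is not among the listed genes and its species is not given. A treatment effect on *Myc* stays open and untested.

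Male-biased and female-biased liver genes were mostly higher with TSA, apart from 3 male-biased genes that were lower, *Gstp1* by 2.08-fold, *Cyp4a12a* by 7.76-fold and *Cyp4a12b* by 112-fold on 2 counts. The highest count of any of the 4 Y-linked genes, which both libraries list, was 0 in either library, under the floor of 3. These counts give no sign of a difference of sex between the animals. They do not exclude one, since neither library shows that reads of these genes were counted, and *Xist* was not listed. A greater share of mature hepatocytes, as in the first pattern, and the treatment stay open and were not tested for these genes.

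Outside the naming rule, the acinar genes *Cela2a* and *Pnlip* were 63.9-fold and 52.9-fold higher against a floor of 3 counts. *Cel*, in no list, had 0 counts without treatment and 56 with TSA. *Amy2a5*, with 0 and 4 counts, *Prss1*, with 0 in either library, and the gut gene *Muc2*, with 1 and 0, had too few counts to be tested. *Clps*, an acinar gene, was at 1.22-fold (0.711 to 2.05) of the untreated level, not called.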
